A study of Mus musculus with 2 samples.

How the data were processed

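Cells were sorted as astrocytes and endothelial cells from whole brains of adult mice, and 1 library was made from each of 2 genotypes, IL34LacZ/+ and IL34LacZ/LacZ. Libraries were made with the 10x Chromium Single Cell 3-prime kit, version v3.1, per the labels' protocols. The matrices hold UMI counts per gene and barcode that the authors produced with Cell Ranger 7.1.0, per the file headers. The genome was mm10 (GRCm38.p6), per the submitters' processing notes. The annotation release, the sort markers, the number of mice and any removal of free RNA were not given in the sources used here. The counts were used as deposited. The smallest barcode total in either file was 500 UMIs, and whether the authors set that limit was not given in the sources used here. The files list 25906 genes, of which 5692 had no UMI in either library. Of these identifiers 25461 were found in the GENCODE M21 annotation of GRCm38, which supplied gene positions. Xist and Meg3 were not among the features.

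Barcodes with at least 1000 UMIs, at least 500 genes and at most 15% of UMIs from mitochondrial genes were kept, leaving 1668 barcodes of the library labelled IL34LacZ/+ and 1175 of the library labelled IL34LacZ/LacZ. All 37 mitochondrially encoded genes, transfer RNA genes included, counted toward that share. Doublets were marked per library with Scrublet as implemented in scanpy 1.11.5, which marked 9 (0.540%) and 7 (0.596%) barcodes, few against the 3.12% and 4.32% expected from the barcode numbers. Marked barcodes were removed, so 1659 and 1168 cells remained. Doublets that were missed can carry transcripts of another class into a sum.

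The cells of both libraries were clustered together without integration, on log-normalized counts, 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and Il34 were left out of the clustering. Clusters were named from 26 marker lists by the highest median log2 fold of a list, which had to reach 1 with at least 3 markers detected in 10% of cells. A cluster stayed unnamed when its top 10 genes held more markers of another class than of its own, or when its median UMI count was below that of its library divided by 3 and no marker was among those genes. Erythrocyte-like clusters also needed a median of 50% haemoglobin UMIs. Clusters of over 50 cells with at least 2 markers of another class among their top 10 genes were clustered again once and each piece was named. That split and details of the scoring were set after first clusters had been seen. Endothelial-like cells were reclustered in the same way, and sub-clusters took the zone with the highest positive score, with at least 3 markers detected and no excess of markers of other classes. The zone rule, and the limit of 1.5% for the median share of ribosomal protein UMIs that marked a sub-cluster as rich in them, were written after the scores and shares of first sub-clusters had been seen. The sub-clusters of weak score depended on the seed and on the numerical setting of the computation, which was fixed to 1 thread.

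Within each class the raw counts were summed per library and divided by the class total to give CPM. Log2 ratios of CPM carry exact conditional binomial 95% intervals, CPM values exact Poisson intervals and shares exact Clopper-Pearson intervals, all for counting error only. Differences of shares carry intervals combined from the exact intervals of both shares by Newcombe's square-and-add method. With 1 library per genotype, cells are not replicates, so no p-value was computed and counts of genes past 2-fold describe these libraries only. Genes with at least 100 UMIs in the class and at least 20 CPM in a library were measured. Named genes were the members of the gene lists and, in endothelial-like and astrocyte-like cells, the 10 genes of highest and 10 of lowest ratio whose direction held after each cell was thinned to 1000 UMIs. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes, unnamed gene models and genes over 10 times more abundant in another class were left out of those 10 and given separately. The direction after thinning rests on few UMIs for the less abundant genes. Intervals of genes picked for extreme ratios do not allow for that choice. Thinning, and leaving out the 2% of cells highest for a gene, reuse the same cells and are no independent check.

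For the gene lists the median log2 ratio of members with at least 30 UMIs was set against 10000 random lists of the same size matched on mean expression in 20 bins, where at least 5 members were measured. A member was counted as higher or lower when its ratio passed 1.5-fold and its interval left out 1. A percentile describes these libraries and is not a test of genotype. The comparisons, the filters, the marker and gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. Other classes with at least 100 cells per library were described in the same way. For a test of carried-over RNA, the choroid plexus epithelium-like CPM profile of each library was multiplied by the ratio of Ttr between the median endothelial-like and the median of those cells and taken off the endothelial-like CPM, before ratios and medians were computed again. A version of that test on the class sums was dropped after its result had been seen, because 1 cell held 51.5% of the endothelial-like Ttr UMIs of the library labelled IL34LacZ/LacZ, and the limit on a full loss was then added.

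The computation was tested on simulated counts drawn from the means of the real genes, with 200 genes changed by known folds. Raising genes lowers the CPM of all others, so estimates were compared with the CPM ratio that the simulation truly held, after a first comparison with the planted fold had missed by that shift. For endothelial-like cells (5996 genes) the intervals covered that ratio for 95.9% of genes and left out 1 for 74.5% of genes raised 1.5-fold and 100% of those raised 2-fold. For astrocyte-like cells (6031 genes) the values were 96.2%, 73.3% and 97.8%. A list raised 2-fold came out above all random lists in both classes. Of lists drawn at random from all measured simulated genes, changed ones included, 3% and 2% lay outside the central 95% range. They came from the same pool as the random lists, so a small share was built in. The simulated sums were drawn gene by gene with counting error alone, without variation between cells or co-variation of genes. The test therefore checks the computation, and not how intervals or percentiles hold where a few cells carry a gene or list members move together.

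The first set of alternatives changed the cell filter, the mitochondrial limit, the doublets, the clustering resolution, joint clustering, the CPM total, the scaling (edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors), the weight of cells, the depth per cell, the floor on genes and, for endothelial-like cells, the zones entered. Alternatives added after the data were seen left mixed clusters unsplit, left out the 2% of cells with most UMIs of each gene, the ribosomal-protein-rich or all unnamed endothelial sub-clusters, or the noncoding mitochondrial genes from the mitochondrial share, and used another clustering seed and a stricter zone score. Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3.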

Results

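Single-cell RNA was measured in cells sorted as endothelial cells and astrocytes from whole brains of adult mice carrying a LacZ allele of Il34. Il34 encodes interleukin-34, which together with Csf1 forms the pair of ligands of the receptor Csf1r on microglia and brain macrophages. The series title ties the work to vascular function and to perivascular macrophages that depend on interleukin-34. There was 1 library from IL34LacZ/+ mice, which the design text treats as wild type, and 1 library from IL34LacZ/LacZ mice, which it treats as knockout. The number of mice per library and the sort markers were not given in the sources used here. The sample titles name astrocytes alone, while the cell type field names both sorted types. The library labelled IL34LacZ/+ held 3901 barcodes with 26679053 UMIs, and the library labelled IL34LacZ/LacZ held 5400 barcodes with 36696941 UMIs. After filtering, 1659 and 1168 cells remained, with a median of 8053 and 10378 UMIs per cell. With 1 library per genotype no test across samples was possible, and no difference below has a replicate check. All intervals are 95% intervals that cover counting error only. Ratios are those of the library labelled IL34LacZ/LacZ over the library labelled IL34LacZ/+.

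The first comparison asked where the targeted gene was detected. Among the named classes of this sort, Il34 tags came mainly from pericyte-like cells, the mural cells of capillaries, and from fibroblast-like cells. The 14 and 10 neuron-like cells held 0 Il34 UMIs, which allows up to 46.5 and 36.9 CPM, so sources outside the sort were hardly measured. In pericyte-like cells Il34 reached 308 CPM (239 to 390, 68 UMIs in 38 cells) in the library labelled IL34LacZ/+ and 516 CPM (432 to 611, 134 UMIs in 48 cells) in the library labelled IL34LacZ/LacZ. In fibroblast-like cells the levels were 312 CPM (247 to 389, 78 UMIs in 22 cells) and 448 CPM (370 to 538, 116 UMIs in 24 cells). Both sorted types were nearly free of Il34, with 1 and 1 UMI in 517 and 310 endothelial-like cells and 1 and 2 UMIs in 265 and 134 astrocyte-like cells. Il34 lies on the minus strand of chromosome 8 at 110741829 to 110805924 in GRCm38 (ENSMUSG00000031750), and its main transcript has 7 exons. The tag of a 3-prime library lies at the 3-prime end of the transcript. The position of the LacZ insertion and the part of Il34 that it removes were not given in the sources used here, and a tag outside the removed part checks nothing. Because Il34 tags were higher where the genotype should lack the gene, each library is named below by its label, and every direction rests on that label. The feature list held no lacZ row.

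Csf1, the other ligand of Csf1r, was found mainly in oligodendrocyte-like cells, at 96.9 CPM (87.0 to 108) and 125 CPM (115 to 136). In astrocyte-like cells Csf1 was 23.5 CPM (17.7 to 30.5, 56 UMIs) and 46.2 CPM (35.3 to 59.3, 61 UMIs), a log2 ratio of 0.98 (0.43 to 1.53). In endothelial-like cells it was 46.0 CPM (38.2 to 55.0) and 57.1 CPM (46.6 to 69.3). Csf1r was found in microglia-like cells, at 2514 CPM (2208 to 2850) in 45 cells and 1097 CPM (803 to 1463) in 14 cells. It was detected in 45 and 11 of them.

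The second comparison concerned the makeup of the sorted cells. Under the settings described above, endothelial-like cells were the largest class in both libraries, with 517 cells (31.2%, 28.9 to 33.5) in the library labelled IL34LacZ/+ and 310 cells (26.5%, 24.0 to 29.2) in the library labelled IL34LacZ/LacZ. Astrocyte-like cells made up 16.0% (14.2 to 17.8) and 11.5% (9.70 to 13.4). Much of both libraries lay outside the sorted types. Choroid plexus epithelium-like cells, which secrete cerebrospinal fluid, were 359 cells (21.6%, 19.7 to 23.7) and 269 cells (23%, 20.6 to 25.6), and myelinating oligodendrocyte-like cells were 253 (15.3%, 13.6 to 17.1) and 233 (19.9%, 17.7 to 22.4). Microglia-like cells were 45 of 1659 (2.71%, 1.99 to 3.61) and 14 of 1168 (1.20%, 0.657 to 2.0).

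**Figure D1:**
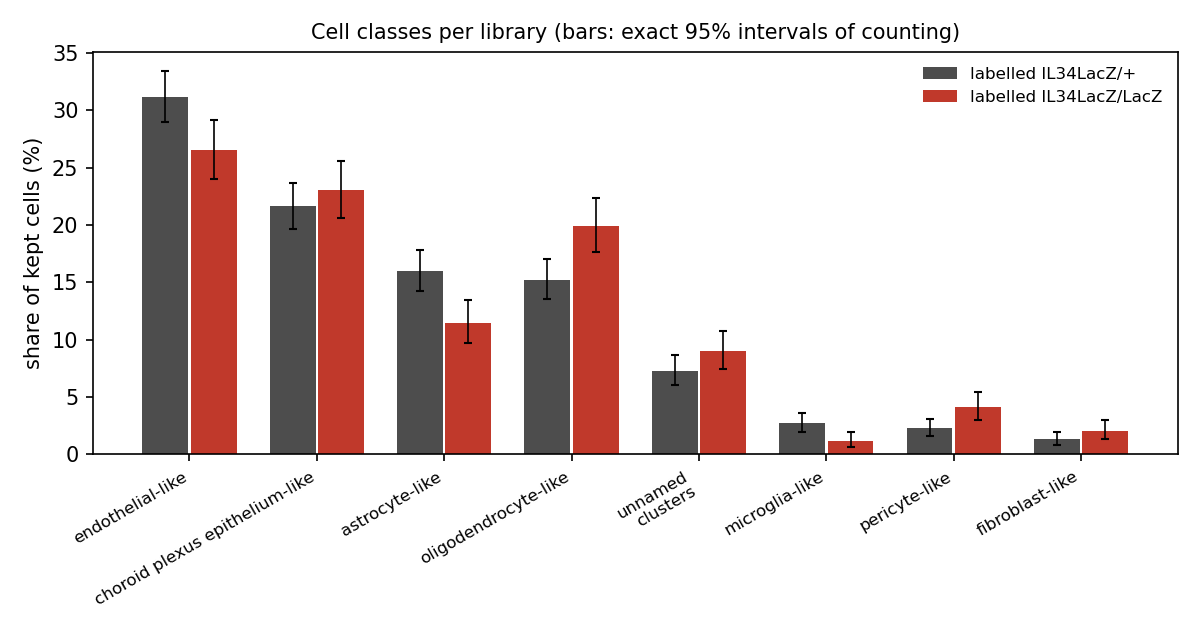
Share of kept cells (%, vertical axis) in 7 named classes and in the unnamed clusters, for the library labelled IL34LacZ/+ (grey) and the library labelled IL34LacZ/LacZ (red). Error bars are exact 95% binomial intervals of counting; the microglia-like share was 2.71% and 1.20%.

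The difference in share was −4.62 percentage points (−8.02 to −1.18) for endothelial-like cells, −4.50 (−7.06 to −1.88) for astrocyte-like cells and −1.51 (−2.56 to −0.43) for microglia-like cells. It was 4.70 points (1.80 to 7.65) for oligodendrocyte-like cells and 1.82 points (0.46 to 3.28) for pericyte-like cells. For choroid plexus epithelium-like cells it was 1.39 points (−1.76 to 4.59) and for fibroblast-like cells 0.73 points (−0.27 to 1.83), both within counting error. Clusters left unnamed held 121 cells (7.29%) and 105 cells (8.99%). Their largest member, with 181 cells (96 and 85), expressed Igfbp5, Slc47a1, Bnc2 and Rspo3. Its highest-scoring list was that of fibroblasts, at a median log2 fold of 3.67. It stayed unnamed because its top 10 genes held more markers of another class. All unnamed clusters together held 10 and 5 Il34 UMIs. Smaller classes were erythrocyte-like (9 and 14 cells), neuron-like (14 and 10), ependymal-like (4 and 5) and neuroblast-like (12 and 2). No cluster was named from the markers of perivascular macrophages, smooth muscle, oligodendrocyte precursors, monocytes, neutrophils or lymphocytes. Each cluster could take only the list with the highest score. Of 9 perivascular macrophage markers, among them Mrc1, Cd163 and Lyve1, at least 3 were detected in 0 of 1659 and in 1 of 1168 kept cells, which sets no limit on such cells where few UMIs were counted per cell.

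The sort sets which cells enter, so these shares do not measure brain composition. With no filter on cells the oligodendrocyte-like difference turned to −2.90 points and the pericyte-like difference fell to 0.042 points. With at least 2000 UMIs per cell no cluster was named microglia-like. In the library labelled IL34LacZ/LacZ, choroid plexus epithelium-like cells outnumbered endothelial-like cells under some settings. The numbers were 436 and 289 with no filter on cells, 429 and 301 with the mitochondrial limit on protein-coding genes, and 262 and 224 at resolution 2.

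Among endothelial-like cells, arterial-like, venous-like and fenestrated-like sub-clusters were found in both libraries. Arterial-like cells, with Gkn3, Bmx and Vegfc, were 32 of 517 (6.19%, 4.27 to 8.63) and 16 of 310 (5.16%, 2.98 to 8.25). Fenestrated-like cells, with Plvap, were 9 (1.74%, 0.799 to 3.28) and 8 (2.58%, 1.12 to 5.02). Capillary-like cells were 204 (39.5%, 35.2 to 43.8) and 120 (38.7%, 33.3 to 44.4), and venous-like cells were 71 (13.7%, 10.9 to 17.0) and 57 (18.4%, 14.2 to 23.2). Unnamed sub-clusters held 201 (38.9%) and 109 (35.2%). One of them, rich in ribosomal protein transcripts and led by Igfbp5, Fabp4, Gng5 and Fos, held 74 cells (14.3%, 11.4 to 17.6) and 23 cells (7.42%, 4.76 to 10.9). Another, with the erythrocyte genes Hbb-bt, Hba-a1, Hbb-bs and Alas2 as leading genes, held 61 and 52 cells, and another, led by the neuronal genes Nrxn3, Cntnap2, Kcnip4 and Rbfox1 among others, held 66 and 34 cells. The interval of the difference included 0 for each of the 4 zones. With another seed of the clustering the capillary-like sub-clusters held 282 and 150 cells and the venous-like 13 and 19, so the sizes of these zones depended on the clustering. The capillary-like sub-clusters had scores of only 0.23 to 0.53, and the larger venous-like sub-cluster, with 58 and 38 cells, only 0.09. The smaller venous-like sub-cluster, with 13 and 19 cells, scored 3.13 and had Slit2, Adgrg6, Il1r1 and Vcam1 among its leading genes. With zones named at a median log2 fold of 1, no sub-cluster was capillary-like and the venous-like cells were 13 and 19. The venous-like difference was above 0 in every setting, from 3.61 to 5.90 points, but Vcam1 and Icam1, which differed between the libraries, are among the markers that name this zone.

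The third comparison asked how transcript levels differed in endothelial-like cells. The measured genes lay close together in the libraries, with 92.2% of 6159 genes within 1.5-fold and a median log2 ratio of −0.08. The leukocyte adhesion molecule Vcam1 was 3.97-fold higher in the library labelled IL34LacZ/LacZ, at 36.2 and 144 CPM (log2 1.99, 1.64 to 2.34), and the interleukin-1 receptor Il1r1 was 2.25-fold higher, at 148 and 333 CPM (log2 1.17, 0.98 to 1.36). The adhesion molecule Icam1 was 2.42-fold higher, at 26.4 and 63.8 CPM (log2 1.27, 0.83 to 1.72). With zones named without these 3 genes, venous-like cells held 55 and 210 Vcam1, 37 and 91 Icam1 and 325 and 534 Il1r1 UMIs. All other endothelial-like cells held 41 and 49, 33 and 24, and 68 and 67. These are UMIs and not CPM, and in those other cells the log2 CPM ratio of Il1r1 was 0.64 (0.13 to 1.14). A cluster with Il1r1 and Icam1 among its leading genes held 54 and 46 cells, and a venous-like sub-cluster with Il1r1 and Vcam1 held 13 and 19. These values do not separate the level per cell from the number of such cells. Cldn5, the main claudin of brain endothelial tight junctions, was lower, at 2308 and 1489.8 CPM (log2 −0.63, −0.70 to −0.57). The arterial kinase gene Bmx was lower too, at 92.8 and 43.8 CPM (log2 −1.08, −1.47 to −0.71).

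Counting both directions, 28 genes were more than 2-fold higher and 32 more than 2-fold lower in that library. Of these, 17 and 10 were far more abundant in another cell class. Clusters led by markers of 2 classes had been split once, a step added after the first clusters were seen. Without it, 113 genes were more than 2-fold higher and 20 more than 2-fold lower, on 512 and 307 cells, so these counts rest on which cells enter the class. The other highest ratios belonged to Slit2, Adamts9 (log2 1.45, 1.17 to 1.73), Ptgs2 (1.31, 0.78 to 1.86), Prdm15 (1.31, 0.71 to 1.93), Mgp (1.3, 1.04 to 1.55), Adgrg6 (1.27, 0.80 to 1.75) and Zbtb16 (1.14, 0.59 to 1.70). Slit2, an axon and vessel guidance ligand, was at 17 and 247 UMIs, of which 1 cell held 78.5% in the library labelled IL34LacZ/LacZ. The other lowest belonged to Wnt5b (log2 −1.75, −2.47 to −1.10), Foxf1 (−1.39, −2.04 to −0.79), Usp1 (−1.32, −2.02 to −0.67), Babam1 (−1.28, −1.97 to −0.64), Col14a1 (−1.20, −1.92 to −0.53), Alox12 (−1.14, −1.81 to −0.52), Dpm3 (−1.11, −1.69 to −0.56), Gemin5 (−1.10, −1.81 to −0.44) and Tec (−1.10, −1.58 to −0.64).

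For 6 of the 10 higher genes a single cell held more than 25% of the UMIs in a library, against 1 of the 10 lower genes. Without the 2% of cells with most UMIs of each gene, Il1r1 stood at log2 1.53 (1.26 to 1.80), Vcam1 at 1.19 (0.56 to 1.84), Icam1 at 0.34 (−0.40 to 1.07), Ptgs2 at 0.04 (−1.06 to 1.10) and Mgp at −0.46 (−1.05 to 0.11). Of the 10 higher genes 7 stayed over 1.5-fold, counting Slit2 with 0 and 5 UMIs left, and of the 10 lower genes 10 did. Transcripts of other cells included the erythrocyte gene Alas2 (log2 3.98, 3.16 to 4.93) and the neuronal gene Nrxn3 (1.82, 1.47 to 2.18) among the higher ones. The neuronal gene Kcnip4 (−1.84, −2.43 to −1.28) and the astrocyte connexin Gja1 (−1.05, −1.50 to −0.62) were among the lower ones. Haemoglobin transcripts were higher in all 4 large classes, with Hbb-bs at log2 3.93 in endothelial-like, 2.51 in astrocyte-like, 1.16 in choroid plexus epithelium-like and 1.42 in oligodendrocyte-like cells. In the median endothelial-like cell Hbb-bs was at 1363 and 1595 CPM.

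By gene group, 9 of 28 lists had a median below the central 95% range of random lists in endothelial-like cells, 2 lay above that range and 17 within it. Nuclear-encoded genes of oxidative phosphorylation, the mitochondrial respiratory chain, had a median log2 ratio of −0.51, below all 10000 random lists. Of its 44 measured members 14 were lower and 0 higher, among them Ndufa6 (log2 −1.11, −1.66 to −0.59) and Cox5b (−0.88, −1.39 to −0.40). Of the 44, 40 were over 10 times more abundant in choroid plexus epithelium-like cells, and the choroid plexus transcript Ttr stood at 1489 and 975.4 CPM in the median endothelial-like cell. Interferon response genes had a median of −0.40, also below all random lists, with 3 of 26 members lower, Ifit3 (−1.12, −1.90 to −0.39), Isg15 (−0.68, −1.10 to −0.28) and Ifitm3 (−0.60, −0.81 to −0.40). A cluster of 4 endothelial-like cells with Isg15, Ifitm3, Ifit1 and Ifit3 among its leading genes came from the library labelled IL34LacZ/+ alone, and Isg15 was also a leading gene of the ribosomal-protein-rich sub-cluster. Without the 2% of cells highest for each gene the median was −0.38, with Ifit3 at −1.21 (−2.39 to −0.16), Ifitm3 at −0.47 (−0.72 to −0.23) and Isg15 at −0.38 (−0.91 to 0.13). The immediate early list, which responds to cell dissociation, had a median of −0.42 at percentile 0.030, with 6 of 20 lower, among them Jun (−1.03, −1.34 to −0.73) and Jund (−0.79, −1.12 to −0.47). The 13 mitochondrially encoded genes had a median of 0.34, above all random lists, with mt-Nd3 higher (0.62, 0.48 to 0.76).

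Several other groups, some of them vessel-specific, lay below the random range as well. Wnt and beta-catenin targets, the pathway that maintains the blood-brain barrier, had a median of −0.29 at percentile 0.080. Of the 15, Axin2 was lower (log2 −0.77, −1.11 to −0.44), and Apcdd1 was at −0.45 (−0.57 to −0.33) and Sox17 at −0.39 (−0.59 to −0.20). Blood-brain barrier transporters had a median of −0.21 at percentile 0.27. Of the 21, the lactate carrier Slc16a1 was lower (−0.70, −0.85 to −0.55) and the venous amino acid carrier Slc38a5 higher (0.68, 0.40 to 0.96). The lipid carrier Mfsd2a was at −0.51 (−0.71 to −0.31) and the glucose carrier Slc2a1 at −0.24 (−0.34 to −0.14). TGF-beta and BMP genes had a median of −0.25 at percentile 0.41, with Id2, Id3 and Bmp6 lower of 16, Id3 at −0.76 (−0.96 to −0.56). The list of astrocyte signals to vessels, of whose 23 members 10 were measured, had a median of −0.49 at percentile 0.010. Edn1, Edn3, Apoe and Tgfb2 were lower. A cluster of endothelial-like cells with Edn1, Tgfb2 and Mfsd2a among its leading genes held 18 and 3 cells, and another with Slc16a1 among its leading genes held 83 and 22 cells. Without the 2% of cells highest for each gene, Edn1 stood at −0.74 (−1.06 to −0.43), Tgfb2 at −0.68 (−0.87 to −0.49) and Slc16a1 at −0.70 (−0.87 to −0.53). Cholesterol synthesis had a median of −0.44 at percentile 0.46, with Insig1 and Sc5d lower of 15. Glycolysis and lactate genes had −0.33 at percentile 0.52, with Ldhb, Aldoc and Slc16a1 lower and Gys1 higher of 18. The astrocyte calcium list was above the range at 0.21, percentile 99.2, with Kcnma1, Slc8a1, Pla2g4a and Atp2b4 higher of 11. Of the Kcnma1 UMIs in the library labelled IL34LacZ/LacZ, 1 cell held 79.2%.

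The remaining lists in endothelial-like cells lay within the random range. Junction genes had a median of −0.15 at percentile 8.49, and of the 15 only Cldn5 was lower. Angiogenesis, VEGF, angiopoietin and Notch genes had −0.19 at percentile 2.98, with Vegfc, Unc5b and Dll4 lower and Plaur and Angpt2 higher of 21. Leukocyte adhesion and inflammation had 0.02, with Vcam1, Icam1, Il1r1 and Cxcl10 higher and Icam2 lower of 14. All Cxcl10 UMIs, 1 and 35, came from 1 cell per library. Vascular tone and nitric oxide had −0.02, with Edn1 (log2 −0.78, −1.04 to −0.53) and Alox12 lower of 16 and Nos3 at −0.09 (−0.25 to 0.06). Shear stress genes had −0.04, with Klf2 (−0.79, −0.96 to −0.62) and Klf4 (−0.60, −0.78 to −0.42) lower of 11. Caveolae and transcytosis had −0.21, basement membrane 0.02, hypoxia −0.24, MHC class I −0.14, heat shock 0.01, glucocorticoid response −0.04 and circadian genes 0.03. Of the astrocyte lists, endfoot genes had −0.31, glutamate handling −0.22, reactive genes −0.07, synapse-related factors −0.09 and lipid transport −0.11.

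**Figure D2:**
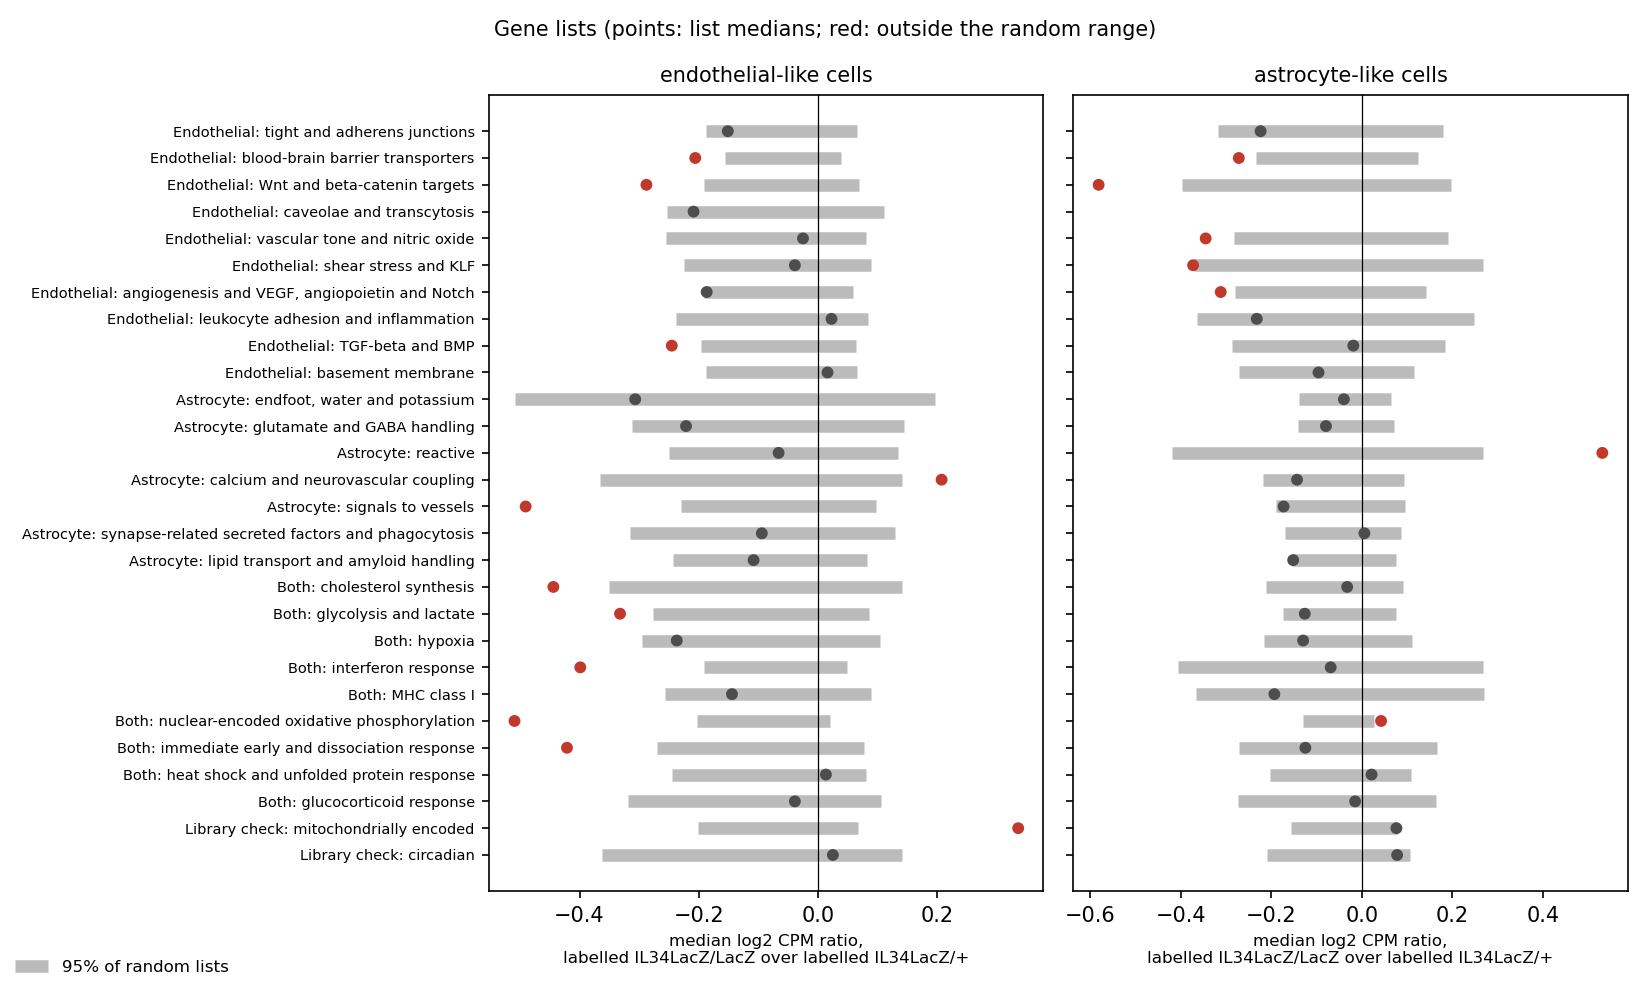
Median log2 CPM ratio (horizontal axes) of each gene list in endothelial-like (left) and astrocyte-like cells (right), library labelled IL34LacZ/LacZ over library labelled IL34LacZ/+. Grey bars span 95% of 10000 expression-matched random lists and red points lie outside them; oxidative phosphorylation stood at −0.51 and 0.04.

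The ribosomal-protein-rich sub-cluster moved with several of these groups. Without it the median was −0.24 for oxidative phosphorylation, 0.02 for immediate early genes and −0.18 for glycolysis, while Wnt targets stayed at −0.29 and barrier transporters at −0.18. In capillary-like cells alone, oxidative phosphorylation was at −0.11, interferon response at −0.04, cholesterol synthesis at −0.06, Wnt targets at −0.17 and barrier transporters at −0.12. With edgeR TMM or DESeq2 size factors the median over all genes moved by about 0.07, and barrier transporters stood at −0.13 under either. The medians of vascular tone, shear stress, glucocorticoid and reactive genes moved to 0.05, 0.03, 0.03 and 0.01 under TMM. Oxidative phosphorylation stood at −0.24 with marked doublets kept and at −0.31 without the split of mixed clusters, which also moved heat shock genes to 0.43.

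The fourth comparison asked the same of astrocyte-like cells. Their 4 clusters held 116 and 44, 69 and 43, 64 and 39, and 16 and 8 cells. The first had Agt and Slc6a11 and the second Npy, Slc1a2 and Fabp7 among their leading genes, and the ratios below take all 4 together. Slc1a2, the main glutamate transporter, was at 4708 and 5039.8 CPM (log2 0.10, 0.05 to 0.14), the water channel Aqp4 at 698 and 721 CPM (0.05, −0.07 to 0.16) and Glul, glutamine synthetase, at 928 and 882 CPM (−0.07, −0.18 to 0.03). Fabp7, a fatty acid binding protein of radial glia and astrocytes, was lower, at 323 and 127 CPM (log2 −1.34, −1.59 to −1.10), and Csf1 was 1.97-fold higher. The vessel-stabilising ligand Angpt1 was lower, at 166 and 102 CPM (−0.70, −0.99 to −0.41).

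Of 6063 measured genes, 94.6% were within 1.5-fold, 25 were more than 2-fold higher and 24 more than 2-fold lower, with 20 and 6 of these far more abundant in another class. The higher genes under the naming rule were Trim23 (log2 1.16, 0.63 to 1.71), Cradd (1.13, 0.64 to 1.62), Pigl (1.08, 0.49 to 1.66), Cep57l1 (1.0, 0.49 to 1.51), Csf1, Stx6 (0.96, 0.50 to 1.41), Nars2 (0.91, 0.34 to 1.48), Enox1 (0.89, 0.44 to 1.33), Fgf13 (0.86, 0.59 to 1.13) and Acad10 (0.85, 0.26 to 1.44). The lowest was Npy, neuropeptide Y, at 317 and 3 UMIs in 9 and 3 cells (log2 −5.87, −8.16 to −4.31). It was followed by Plppr4 (−2.09, −3.09 to −1.21), the receptor genes Gabrg3 (−1.72, −2.12 to −1.34), Grik1 (−1.58, −2.42 to −0.83) and the kainate receptor partner Neto2 (−1.58, −2.42 to −0.83). Cyp2u1 (−1.42, −2.24 to −0.68), Fabp7, Cggbp1 (−1.15, −1.84 to −0.50), Psmg2 (−1.12, −1.80 to −0.49) and Fmo1 (−1.09, −1.77 to −0.46) completed the 10. For 4 of the 10 lower genes a single cell held more than 25% of the UMIs in a library, against 1 of the 10 higher genes. Without the 2% of cells highest for each gene, 9 of the 10 higher and 7 of the 10 lower stayed over 1.5-fold, counting Npy with 11 and 0 UMIs left. Plppr4, Grik1 and Fabp7 were not among these, with Fabp7 at −0.52 (−0.81 to −0.24). Transcripts of other cells differed more. The choroid plexus gene Ttr was at log2 2.07 (2.02 to 2.13), with 47.1% of its UMIs in 1 cell of the library labelled IL34LacZ/LacZ, but its level in the median astrocyte-like cell was lower there, at 1267 and 806 CPM. The endothelial genes Flt1 (−2.18, −2.89 to −1.54) and Slco1a4 (−1.76, −2.57 to −1.03) were lower, with 33.3% and 22.7% of their UMIs in 1 cell of the library labelled IL34LacZ/+.

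In astrocyte-like cells 20 of 27 lists lay within the random range, 5 below and 2 above. The reactive astrocyte list was above, with a median of 0.53 at percentile 99.9 over 9 measured members. Of these Cp, ceruloplasmin (log2 1.85, 0.80 to 2.99), and Cryab (0.91, 0.63 to 1.20) were higher and Vim, vimentin (−1.81, −3.34 to −0.56), was lower. Gfap, the classical reactive marker, was at 0.53 (−0.39 to 1.44) on 25 and 20 UMIs. With at least 2000 UMIs per cell the reactive median was 0.03, and 56.0% of the Cryab UMIs of the library labelled IL34LacZ/LacZ were in 1 cell. Oxidative phosphorylation was at 0.04, percentile 98.9, with 0 of 44 members past the limits, and its sign turned to −0.01 with no filter on cells. The lists below the range were endothelial ones. Wnt targets had a median of −0.58 with Lef1, Nkd1, Apcdd1 and Ppard lower of 10, and −0.00 without the cells highest for each gene. Barrier transporters had −0.27 with Slco1a4 and Abcb1a lower of 16, and angiogenesis genes −0.31 with Flt1 lower of 10. Vascular tone genes had −0.35 with Ptgds lower of 6, but 0.11 with no filter on cells. Shear stress genes had −0.37 with Klf6 and Txnip lower and Adamts1 higher of 6. Of the Ptgds and Txnip UMIs in the library labelled IL34LacZ/+, 1 cell held 65.3% and 68.1%.

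Among the astrocyte lists within the range, endfoot, water and potassium genes had a median of −0.04 and glutamate and GABA handling −0.08. The calcium list had −0.14 and synapse-related factors 0.01. Lipid transport had −0.15 with Fabp7 lower of 18 and Apoe at log2 −0.36 (−0.40 to −0.33). Signals to vessels had −0.17 with Csf1 and Fgf2 (1.25, 0.24 to 2.28) higher and Angpt1 lower of 16, and Vegfa at −0.34 (−0.49 to −0.20). Cholesterol synthesis had −0.03, glycolysis −0.13, hypoxia −0.13, interferon response −0.07, MHC class I −0.19, immediate early genes −0.13 (0.81 with no filter on cells and −0.44 at resolution 0.5), heat shock 0.02 and glucocorticoid response −0.02. Junction genes had −0.22, leukocyte adhesion −0.23, TGF-beta genes −0.02 and basement membrane −0.10. The mitochondrially encoded genes were at 0.08 and circadian genes at 0.08. Fewer than 5 caveolae genes were measured.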

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

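Among the tests in this part, that on the ribosomal-protein-rich sub-cluster was set out before its result was seen, and those on a shift of the whole library and on carried-over RNA were chosen afterwards.

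Nuclear-encoded oxidative phosphorylation genes had a median log2 ratio of −0.51 in endothelial-like cells, with 14 of 44 members lower, and of −0.10 in oligodendrocyte-like, 0.044 in choroid plexus epithelium-like and 0.042 in astrocyte-like cells, each with 0 of 44 members past the limits, and the difference between classes was not tested. Of these other 3 classes 1 had a median below its random range, and that of choroid plexus epithelium-like cells spanned −0.014 to 0.057, which argues against a shift of that size shared by all classes, although the astrocyte value turned to −0.011, −0.00070 and −0.085 under other settings and to −0.79 at a mitochondrial limit of 5%, on 86 and 21 cells. Relative to the median of all genes the endothelial value was −0.43, it was −0.46 with the choroid plexus profile taken off at the share that Ttr gave in the median cell (0.504% and 0.404%), and a full loss of the first share would give −0.13, which argues against less carried-over choroid plexus RNA as the whole cause. Without the ribosomal-protein-rich sub-cluster, which held 14.3% and 7.42% of endothelial-like cells, it was −0.17, between the bounds of the test, as was its first value before the computation was fixed to 1 thread, and since the median itself was −0.44 without all unnamed sub-clusters but −0.11 in capillary-like cells alone, −0.24 with doublets kept, −0.30 after thinning and −0.31 with mixed clusters unsplit, a change in the share of that sub-cluster cannot be told apart from a change within the cells. Genotype may also contribute and stays open, since it coincides with the library.

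Immediate early genes had a median of 0.92 in choroid plexus epithelium-like cells, 0.44 in oligodendrocyte-like cells and −0.42 in endothelial-like cells, and differences between classes were not tested. The endothelial value turned to 0.017 without the ribosomal-protein-rich sub-cluster and to 0.053 without the unnamed ones. In choroid plexus epithelium-like cells 1 cell held 43.9% of the Fos UMIs of the library labelled IL34LacZ/LacZ.

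Haemoglobin differed in barcodes that the comparisons did not use and in those that they did. More than 50% of UMIs came from haemoglobin genes in 30.1% (28.9 to 31.3) of the barcodes of the library labelled IL34LacZ/LacZ and in 16.7% (15.6 to 17.9) of those of the library labelled IL34LacZ/+. Among kept endothelial-like cells Hbb-bs had 3956 and 40872 UMIs, with 19.4% of the latter in 1 cell.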

How the results depend on the processing

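The alternatives that left mixed clusters unsplit, that left out cells highest for a gene, the ribosomal-protein-rich or unnamed sub-clusters or the noncoding mitochondrial genes, and those with another seed or zone score, were added after the data were seen. Over 72 results and 1147 comparisons with an alternative, 1002 values stayed within the bounds set for no change, 137 moved and 8 changed the sign of a value that lay outside its random range or whose interval left out 0. Class shares moved or changed sign in this way in 8 of 72 comparisons, zone shares in 3 of 25, counts of genes in 33 of 74 and list medians in 101 of 976. The cause was not tested for any of these unless said. For shares, the bounds concern the difference between the libraries and not the size of a class or zone. Capillary-like cells went from 204 and 120 to 0 and 0 with zones named at a median log2 fold of 1, which counted as no change. No alternative that pairs or leaves out replicates applies with 1 library per genotype, and the depth of the smaller classes limits every count.

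With no filter on cells the differences in share were −2.57 points for choroid plexus epithelium-like, −2.90 for oligodendrocyte-like, 0.042 for pericyte-like, −0.66 for fibroblast-like and 7.30 for unnamed cells. With at least 2000 UMIs the microglia-like difference was 0, because no cluster was named so, and among endothelial-like cells it was −4.33 for arterial-like, −6.40 for fenestrated-like and 3.75 for unnamed cells. Clustering each library alone gave −3.27 for unnamed cells, and the mitochondrial limit on protein-coding genes gave 7.88 for choroid plexus epithelium-like cells.

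In endothelial-like cells the counts of genes over 2-fold higher and lower were 6 and 5 after thinning to 1000 UMIs, 145 and 243 with at least 30 UMIs and no CPM floor, and 10 and 3 with at least 300 UMIs, where the number of measured genes was 1721, 9671 and 2927. They were 113 and 20 with mixed clusters unsplit, 8 and 4 in capillary-like cells alone and 12 and 15 without the unnamed sub-clusters. The lower count was 80 at a mitochondrial limit of 5%, and 21 under DESeq2, under TMM, with totals free of mitochondrial, ribosomal protein and haemoglobin genes, and without the ribosomal-protein-rich sub-cluster. The higher count was 9 without the 2% of cells highest for each gene. The immediate early median turned to 0.017 without the ribosomal-protein-rich sub-cluster and 0.053 without the unnamed ones.

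In astrocyte-like cells the counts of higher and lower genes were 14 and 39 with at least 2000 UMIs, 10 and 12 with the mitochondrial limit on protein-coding genes, 5 and 1 after thinning, 130 and 217 with at least 30 UMIs and no CPM floor, and 9 and 4 with at least 300 UMIs. The lower count was 7 with no filter on cells, 235 at a mitochondrial limit of 5% and 39 with the mean of per-cell CPM. The higher count was 53 with doublets kept and 5 without the 2% of cells highest for each gene. The oxidative phosphorylation median turned to −0.011 with no filter on cells, −0.79 at a mitochondrial limit of 5%, −0.00070 with at least 300 UMIs and −0.085 without the cells highest for each gene. The vascular tone median turned to 0.11 with no filter on cells. The immediate early median, −0.13 and within its random range, was 0.81 with no filter on cells, 0.50 with doublets kept, 0.51 with each library clustered alone and −0.44 at resolution 0.5.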

Other observations

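The tests on microglia-like cells and on Il1r1 in this part were all chosen after their results had been seen.

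Choroid plexus epithelium-like cells differed between the libraries in a small set of genes. Of 4516 measured genes 53 were over 2-fold higher in the library labelled IL34LacZ/LacZ and 3 over 2-fold lower, and 44 of the higher ones were far more abundant in another class. Srsf5, a splicing factor, was higher, at 70.0 and 171 CPM (log2 1.29, 1.10 to 1.48), and stood at 1.35 (1.15 to 1.56) without the 2% of cells highest for it. Trpm3, a cation channel, was at 1.22 (1.14 to 1.3) with all cells and 0.06 (−0.04 to 0.16) without those. Ttr, transthyretin, the main secreted protein of this epithelium, was at 286469 and 236274 CPM (−0.28, −0.28 to −0.27). Heat shock genes had a median of 0.17 and mitochondrially encoded genes 0.10, both above the random range, and angiogenesis genes −0.35 and synapse-related genes −0.11, both below it.

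In oligodendrocyte-like cells 15 of 6595 genes were over 2-fold higher and 15 over 2-fold lower, of which 9 and 10 were far more abundant in another class. The immediate early genes Ier2 (log2 1.22, 0.88 to 1.58), Btg2 (1.21, 0.90 to 1.53) and Egr1 (0.77, 0.61 to 0.92) were higher and the chaperone Hspa1b (−1.0, −1.21 to −0.79) and Ogdhl (−1.64, −2.17 to −1.14) lower. Ttr, a choroid plexus transcript, was at −1.89 (−1.95 to −1.83), with 50.5% of its UMIs in 1 cell of the library labelled IL34LacZ/+. Its median over cells was 968 and 620.5 CPM.

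Microglia-like cells were 45 of 1659 in the library labelled IL34LacZ/+ and 14 of 1168 in the library labelled IL34LacZ/LacZ, in a sort for other cells. Per cell of the other named classes outside the gate, the ratio was 0.357 (0.230 to 0.539) with no filter on cells and 0.370 (0.187 to 0.686) with it, which argues against the filters and against a smaller leak of every class as the whole cause. An exchange of the labels cannot be told apart from the labelled order, since the Il34 ratio of 1.56 (1.26 to 1.92) in pericyte-like and fibroblast-like cells came with Il34 tags in both libraries and the removed part of the gene is not known here. A lower yield of microglia in the IL34LacZ/LacZ brain, and a difference between sorts in that class alone, may each account for it, and neither was tested. The 10 microglia markers had a median log2 ratio of −0.59 within these cells, and the intervals of 6 lay below 0, for example P2ry12 at −1.77 (−2.48 to −1.13) and C1qa at −0.25 (−0.48 to −0.02). Csf1r was detected in 45 of 45 and 11 of 14 of these cells, and the 1 kept cell with perivascular macrophage markers was among the 14. A single cell held 97.7% of the 3380 Hbb-bs UMIs among the 41933 UMIs of the library labelled IL34LacZ/LacZ in this class. In the other library it was 93.4% of 3646 among 97068. Such UMIs lower the CPM of every marker by the same factor. The intervals of P2ry12 and C1qa did not overlap, which argues against that dilution as the whole cause of the lower markers. Lower levels within microglia cannot be told apart from other cells in the class.

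Il1r1 was singled out after tests on Vcam1, Icam1, Il1r1 and Cxcl10 together, then on the first 3, had been seen, and a first test by zone was dropped because Vcam1 and Icam1 are zone markers. Without the 2% of cells highest for it, its log2 ratio was 1.53 (1.26 to 1.80) against 1.17 with all cells. Icam1 fell to 0.34 and Vcam1 to 1.19. The Il1r1 ratio thus did not rest on those cells alone. In zones made without these 3 genes, venous-like cells held 325 and 534 of its UMIs, all other endothelial-like cells 68 and 67. In those other cells the log2 CPM ratio of Il1r1 was 0.64 (0.13 to 1.14). A small group of cells as its source is not excluded, since the test drops a share of all cells and the gene was chosen after such tests. Within venous-like cells, clustered and named without Il1r1, Vcam1 and Icam1, the log2 ratio of Il1r1 was 0.87 (0.67 to 1.07), and these cells made up 13.7% (10.9 to 17.0) and 17.7% (13.7 to 22.5). The lower end of that interval falls short of the limit of the test, so a larger venous share as a partial cause cannot be told apart from a higher level within cells. The value within venous-like cells does not hold the mix of these cells fixed either. A genotype effect may remain and is untested.

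Genes near Il34 were set beside all others, and the difference was not tested. Of 33 measured genes within 5 Mb of Il34 on chromosome 8, 3 differed over 1.5-fold in endothelial-like cells (9.09%), against 471 of 6121 others (7.69%). The values were 1 of 30 (3.33%) and 321 of 6029 (5.32%) in astrocyte-like, 1 of 18 (5.56%) and 223 of 4493 (4.96%) in choroid plexus epithelium-like, and 1 of 34 (2.94%) and 157 of 6557 (2.39%) in oligodendrocyte-like cells. The median absolute log2 ratio of near and other genes was 0.159 and 0.187 in endothelial-like, 0.224 and 0.177 in astrocyte-like, 0.210 and 0.136 in choroid plexus epithelium-like, and 0.141 and 0.136 in oligodendrocyte-like cells. Over 5386 genes with at least 50 UMIs in each of the 4 large classes, none outside the haemoglobin genes was over 1.3 times higher in all 4. Genes over 1.3 times lower in all 4 included Filip1l on chromosome 16 (log2 −0.79 in endothelial-like and −1.41 in choroid plexus epithelium-like cells), Rnaset2a and Rnaset2b on chromosome 17, and mt-Nd6. Rnaset2a and Rnaset2b are near-identical copies that reads may not separate, at −0.83 and −0.93 in endothelial-like cells. Of the sex-linked genes, Ddx3y had 1710 and 1204 UMIs and Uty 1880 and 1077, so both libraries held male cells. Whether either also held female cells is not known, since Xist was not among the features.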
